A study of Synechocystis sp. PCC 6803 with 8 samples.

How the data were processed

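RNA of the glucose-tolerant Synechocystis wild type and of 3 strains was measured on 8 single-colour custom arrays, 2 biological replicates for each of WT, NsiR4oex, ΔnsiR4 and ΔnsiR4::oex. Per the labels, cultures grew at 30 °C under 50 to 80 µmol of light in copper-free medium with 20 mM TES at pH 8, received 2 µM CuSO4 to induce the construct and were sampled after 12 h. Per the labels, 2 µg of RNA was labelled with Cy3 directly, without cDNA synthesis.

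The intensity values in the scanner files were made with Agilent Feature Extraction 10.7.3.1, per the file headers, with spatial detrending, background taken from the negative control spots and multiplicative detrending, and they were not normalized between arrays. The deposited value table is on the log2 scale and its columns followed the log2 mean signal of the same array (lowest r 0.999), with sorted columns that differed by at most 0.0562, which is the form that quantile normalization gives. Per the labels, the authors used limma, for which no version was stated. The deposited table was used only as an alternative, and 0 of its columns of values were left unused.

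The processed intensity was taken from the scanner files as deposited, converted to log2 and set relative to the 75th percentile of the array. Log2 values were averaged over the 2 spots of a probe and then over the probes of a feature. A probe was kept if it was well above background, by the scanner's own call, on both arrays of at least 1 group, which kept 16418 of 20363 probes and left out 1116 of 8830 features. There were 415 probe sequences that stood under several feature names, and these names were tested as separate features. Features were named as in the files. Symbols came from the gene lists fixed in advance and from general knowledge of the organism, since 0 locus tags matched the reference table of gene names.

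As a measure of depth, the share of spots well above background ranged from 67.8% to 87.1%, the local background from 35 to 40 intensity units and the signal of the negative controls from 1243 to 2191. No spot was saturated and at most 28 spots of an array were marked as outliers by the scanner. Features near background have compressed fold changes, so for a called feature with a wholly dim group a lower bound is given where it exceeded 1-fold and was lower than the fitted change, and otherwise only the direction. In the mean construct effect, the same raised mean stood in for each dim group before both effects were averaged. These bounds hold for the reported processing only.

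Slide and scan were read from the scanner files, and each of the 2 slides held 4 arrays. Group means were fitted with limma 3.58.1 in R 4.3.3 to all 8 arrays with a shared estimate of the spread, followed by empirical Bayes moderation. Comparisons were NsiR4oex with WT, ΔnsiR4 with WT, ΔnsiR4::oex with ΔnsiR4, ΔnsiR4::oex with WT, the mean of both construct effects and their difference. A feature was called at a Benjamini-Hochberg adjusted p under 0.05 over 7714 features, and the count with an absolute log2 fold change of at least 1 was recorded. All p-values of single features are from limma. Gene lists were tested with camera at a preset correlation of 0.01, with an estimated correlation and with fry, adjusted over the 14 lists. A list of ribosomal protein genes could not be formed because the files hold no symbols, and plasmid genes were taken by the number in the locus tag.

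The features named were set by a rule before the data were examined. It named 8 genes of nitrogen control and copper response, and nsiR4 itself, which no feature is named after. It also named the 10 highest and the 10 lowest called features per comparison, up to 4 called members of each list or the 2 with the lowest adjusted p, and features called in both construct comparisons or in opposite directions on deletion and with the construct. Members of lists that were not called are covered by the counts and p-values alone, and all 205 results of named features are covered by the totals for the alternatives. Neighbours of nsiR4 were not assessed, since the files give no positions. Further features named in the text, such as IsrR-0-x in ΔnsiR4, were singled out after their values were seen.

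The script was tested on simulated data with 50 of 7714 features changed at each size. All sizes were added to the same data, with noise independent between features and without shared differences between replicates. The shares recovered there need not hold for the arrays themselves. For a log2 change of 1 it recovered 74% in NsiR4oex against WT, 74% in ΔnsiR4 against WT, 82% in ΔnsiR4::oex against ΔnsiR4, 84% in ΔnsiR4::oex against WT and 94% in the mean construct effect, and for changes of 2 or more it recovered 100% in each. A simulated shift of 1 in the 25 photosystem II genes of NsiR4oex against WT was recovered, with 1 of 14 lists called. The correlations expected without any effect came from 100 simulations.

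Alternatives were normexp background correction with an offset of 50, quantile normalization, scaling to the median, no filter and a filter on all 8 arrays, the median over probes, the deposited table, a replicate block, a slide block, an intensity trend with robust moderation, only the arrays compared, a fold threshold and leaving out each array. Counting features that share a probe sequence once, a crossed replicate block, a replicate block with only the arrays compared, the differences of gene lists between replicates, and splits of the arrays with slide as a block, were added after seeing the data. Random lists numbered 10000 and a percentile of 97.5 was the bound. RNA pairing was predicted with ViennaRNA RNAduplex 2.7.2, for the stretches covered by array probes only.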

Results

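Gene expression was measured in Synechocystis, a unicellular cyanobacterium, in a glucose-tolerant wild type (WT) and 3 derived strains. NsiR4oex carried a copper-inducible construct that expresses the small RNA NsiR4 in addition to the native gene, ΔnsiR4 lacked the native gene, and ΔnsiR4::oex carried the construct in the deletion background. Each strain was represented by 2 biological replicates, sampled after 12 h with 2 µM CuSO4, so that 8 single-colour arrays were available. The RNA was labelled directly, without cDNA synthesis, which keeps sense and antisense transcripts apart. Each array held 40886 non-control spots, of which between 67.8% and 87.1% were well above background. After removal of features without a probe well above background on both arrays of any strain, 7714 of 8830 features were tested. They comprised 3167 genes, 674 5'UTR features, 1380 antisense features, 1709 internal features, 508 non-coding (NC) features, 43 tRNA or rRNA features and 233 others. Levels are given as log2 signal relative to the 75th percentile of the array, as mean ± SD (n = 2). With 2 arrays per strain, the number of arrays limits the precision of every value. The arrays lay on 2 slides, with WT and NsiR4oex on slide 1 and ΔnsiR4 and ΔnsiR4::oex on slide 2, scanned as scan 1 and scan 2. Both comparisons of a strain with its construct-free parent therefore lay within a slide, whereas in each comparison of a deletion-background strain with WT, slide and strain cannot be told apart.

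The title of the series names NsiR4, nitrogen assimilation and the glutamine synthetase inactivating factor IF7, encoded by gifA (ssl1911). No feature on the array is named nsiR4, so the deleted RNA could not be checked by name. The rule that selected the features with the most extreme changes returned 4 overlapping features, NC-171, NC-174, NC-225 and NC-230, whose probes share at least 33 bases, those of NC-171 and NC-230 being identical, and which were singled out as a group after their values were seen. NC-174 had a level of 4.84 ± 1.14 in WT, 6.92 ± 0.11 in NsiR4oex, -2.25 ± 0.32 in ΔnsiR4 and 6.53 ± 0.10 in ΔnsiR4::oex (SD, n = 2 each). In ΔnsiR4, NC-171 and NC-230 were not well above background on either array, NC-225 was so on 1 array and NC-174 on both. Whether these features are the deleted RNA could not be settled from the array's annotation, and the strain names rest on the labels.

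**Figure D1:**
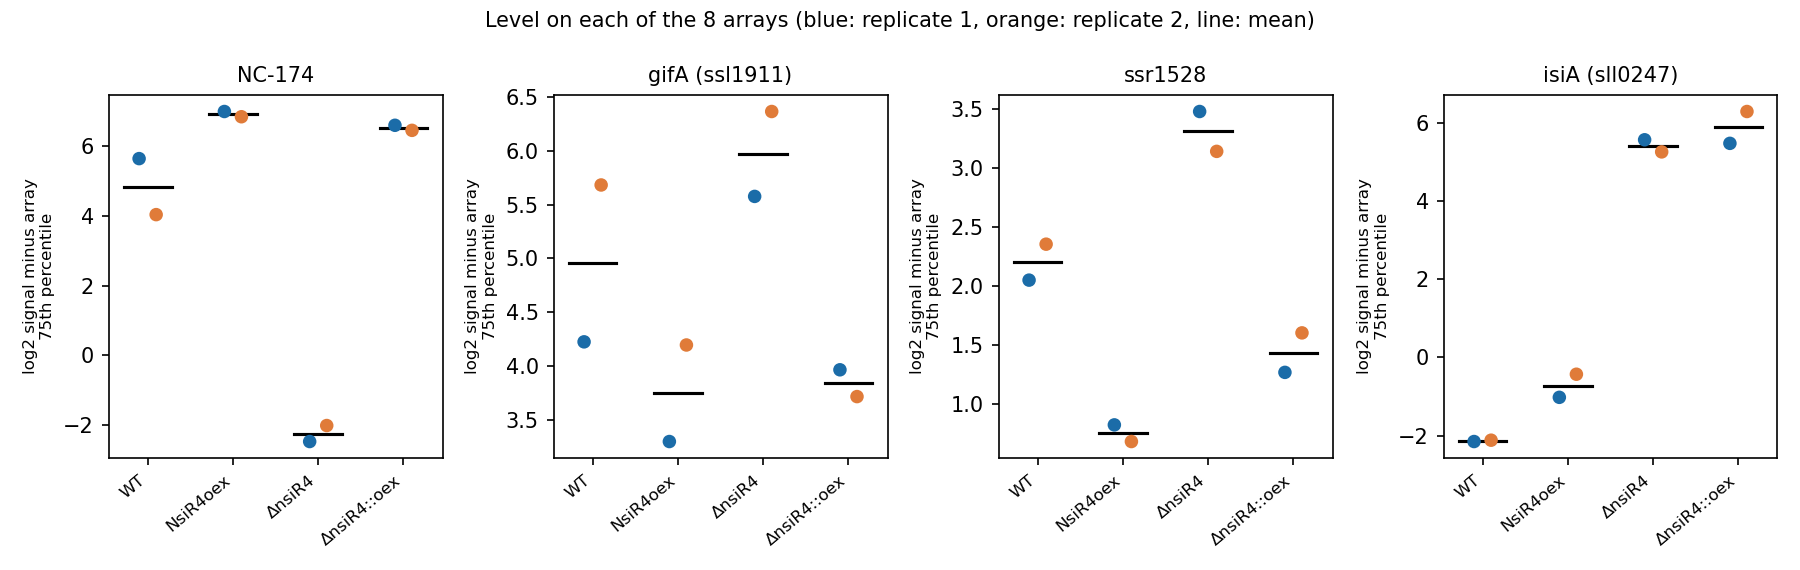
Level of NC-174, gifA, ssr1528 and isiA on each of the 8 arrays, as log2 signal minus the array's 75th percentile; points are single arrays and lines are means of 2 arrays. NC-174 averaged 4.84 in WT and -2.25 in ΔnsiR4, and isiA averaged -2.13 in WT and 5.41 in ΔnsiR4.

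Copper-induced expression of NsiR4 in the wild-type background was compared with WT to ask which transcripts change when the RNA is overproduced. No strain carried the construct without NsiR4, so in either background effects of the construct itself cannot be told apart from those of the RNA. NC-578, a non-coding feature, rose from -5.62 ± 0.29 in WT, where it was not well above background, to -1.62 ± 0.04 in NsiR4oex (SD, n = 2 each), a rise of at least 4.85-fold (limma, adjusted p = 0.000529). For a feature dim in a whole group, this bound sets the brighter group's mean against the dim group's mean of the higher of 2 values on each array, the lowest signal well above background and the feature's own signal. It holds for the reported processing only, and it allows for background and not for the spread between replicates. For NC-578, normexp correction gave a log2 fold change of 1.66 and the deposited values gave 0.69. Both values lie below the bound of 4.85-fold, and the rise was called under each of these settings. NC-578 was also not well above background in ΔnsiR4 (-4.58 ± 0.17), so without the construct it was dim both with and without the native gene. The 4 overlapping features had log2 fold changes between 2.08 and 2.15, with an adjusted p of 0.9997 for each. Without WT replicate 1, limma gave them log2 fold changes between 2.89 and 3.01, and each was called, at an adjusted p = 0.0240 for NC-171 and NC-174 and an adjusted p = 0.00687 for NC-225 and NC-230. Without WT replicate 2 the changes were between 1.24 and 1.31, and none was called. ssr1528, a small open reading frame, had a log2 fold change of -1.45 (SE 0.19, adjusted p = 0.442).

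Of the genes of nitrogen control, gifA had a log2 fold change of -1.21 (SE 0.52) in NsiR4oex, from 4.95 ± 1.03 to 3.75 ± 0.63 (SD, n = 2 each), which ranged from -1.94 without WT replicate 1 to -0.48 without WT replicate 2. gifB (sll1515), which encodes the second inactivating factor IF17, had 0.44 (SE 0.60), glnA (slr1756) for glutamine synthetase type I had -0.92 (SE 0.69), and glnN (slr0288) for type III had -0.28 (SE 0.49). The regulators ntcA (sll1423) and glnB (ssl0707) had 0.14 (SE 0.18) and -0.20 (SE 0.19), and the copper-regulated carriers petE (sll0199) and petJ (sll1796) had -0.13 (SE 0.18) and -0.06 (SE 0.17). None of these 8 genes passed the threshold in limma, where each adjusted p was 0.9997. Their spread in WT was uneven, with SDs of 1.37 for gifB, 1.13 for glnN, 1.03 for gifA and 0.62 for glnA. The SDs were 0.36 for glnB, 0.26 for petJ, 0.18 for petE and 0.11 for ntcA. The signs for gifB, glnA, glnN, glnB, petE and petJ turned when single arrays were left out, gifB for example to -0.53 without WT replicate 1.

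Among the 14 gene lists, 5 shifted in NsiR4oex by camera, a test of a list against all other features. Of the 26 nitrogen assimilation genes, 0 were called by limma, and the list lay lower (median log2 fold change -0.23, adjusted p = 0.00703), with 0.531 as the adjusted p with an estimated correlation. All 9 ATP synthase genes had negative fold changes (median -0.41, adjusted p = 1.06e-06, and adjusted p = 0.427 with an estimated correlation), among them atpH (ssl2615) at -0.44 and atpI (sll1322) at -0.38. The 24 genes of inorganic carbon uptake and the carboxysome lay lower (median -0.32, adjusted p = 1.76e-07, and adjusted p = 0.426 with an estimated correlation), with sbtB (slr1513) at -0.61 and sbtA (slr1512), a bicarbonate transporter, at -0.55. The 17 genes of glycogen and sugar catabolism also lay lower (median -0.20, adjusted p = 0.00237, and adjusted p = 0.281 with an estimated correlation), with glgC (slr1176) at -0.50. The 14 iron response genes lay higher (median 0.24, adjusted p = 0.00304, and adjusted p = 0.401 with an estimated correlation), with isiA (sll0247), a chlorophyll-binding protein made under iron limitation, at 1.41 and perR (slr1738) at 1.19. This shift of the iron list missed the threshold with quantile normalization (adjusted p = 0.0628) and with the deposited values (adjusted p = 0.489). The WT replicates themselves differed by a median of 0.72 for ATP synthase, where all 9 genes were higher in replicate 2, and 0.38 for inorganic carbon (20 of 24). For nitrogen assimilation, replicate 2 minus replicate 1 had a median of -0.27 in WT (7 of 26 higher) and -0.38 in NsiR4oex (6 of 26). In WT this difference was 0.00019 for glycogen and -0.013 for iron. In NsiR4oex it was -0.23 for glycogen (4 of 17 higher) and -0.17 for iron (3 of 14). No member of these 5 lists passed over all features, and adjusted over the list alone 1 did, isiA. No other list passed in camera, the adjusted p being 0.0545 for chaperones and general stress, 0.0842 for both arginine and cyanophycin and cytochrome b6f, 0.379 for photosystem I, 0.418 for photosystem II and 0.860 each for phycobilisome, copper response, phosphate response and plasmid genes.

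In total, limma called 1 of 7714 features in NsiR4oex. An unadjusted p under 0.05 was found for 120 (1.56%), a smaller share than evenly spread p-values would give. Without NsiR4oex replicate 1 the count was 60, without WT replicate 1 it was 5, and it was 0 when only probes well above background on all 8 arrays were tested, since NC-578 was then not tested. The arrays of slide 1 did not group by strain. WT and NsiR4oex replicate 1 correlated at 0.993, against 0.975 between the WT replicates and 0.977 between those of NsiR4oex, and WT replicate 2 was also closest to NsiR4oex replicate 1 (0.984). The low count, and the wide SDs in WT for genes such as gifB, were obtained with these differences between replicates left in the spread. In simulated data of this comparison, 74% of 50 features out of 7714 with an added log2 change of 1 were recovered, and 100% of those with a change of 2. Those data held 50 changed features at each log2 change of 1, 2, 3 and 4. Their noise was independent between features and had no shared differences between replicates. Such recovery cannot be assumed for the arrays, where NC-174 and NC-225, at log2 fold changes of 2.08 and 2.15, were not called.

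Deletion of the native gene was compared with WT to ask which transcripts depend on NsiR4. Iron-responsive genes were among the features with the largest rises in ΔnsiR4, and made up 9 of the 73 called higher. isiA rose from -2.13 ± 0.02 to 5.41 ± 0.22 (SD, n = 2 each), which is 187-fold (log2 fold change 7.54, SE 0.30, limma adjusted p = 0.000116), and isiB (sll0248), encoding flavodoxin, rose at least 26.9-fold. exbB (sll1404) rose by 4.79 (SE 0.37) and exbD (sll1405) at least 5.74-fold, both components of an energy-transducing uptake system. Of the 14 measured genes of the iron list, 9 rose and 1, the repressor gene fur (sll0567), fell by 0.91 on the log2 scale, and the same numbers held adjusted over the list alone. The risers included isiC (sll0249) at 4.30, the ferrous iron transporter gene feoB (slr1392) at 3.59 and the ferric iron binding gene futA1 (slr1295) at 3.37, while the bacterioferritin genes bfrA (sll1341) and bfrB (slr1890) had -0.32 and -0.31. The list's median log2 fold change was 2.95 (camera, adjusted p = 3.24e-08, and adjusted p = 0.126 with an estimated correlation), and fry, which tests whether the members move to the same side, gave an adjusted p of 0.000488.

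The other features with the highest changes in ΔnsiR4 were the isiA transcript features IsiA-1-0-x (6.11), IsiA-2-0-x (6.08) and isiA-0-x (5.77), slr1489-5'UTR (at least 21.1-fold), sll1549 (4.79) and slr1485 (4.69), all with an adjusted p under that of exbD, 0.00203. With the deposited values, exbB had an adjusted p of 0.122 and exbD of 0.111. The lowest were the 4 overlapping features. NC-174 fell by 7.09 (SE 0.46, limma adjusted p = 0.000506) and NC-225 fell by 6.22 (SE 0.47), while NC-171 was at least 102-fold and NC-230 at least 108-fold lower in ΔnsiR4. They were followed by ssl2064 (at least 2.56-fold lower), slr0407-int3 (-2.52), NC-262 (at least 5.57-fold lower), slr1250 (pstB2), slr1260 and sll0793, the latter 2 dim in ΔnsiR4 and without a bound below their fitted change. The value of slr1250, -2.50, averaged 2 probes that disagreed, with -5.11 and 0.11. Leaving out single WT or ΔnsiR4 arrays ended the calls of NC-262 (adjusted p up to 0.0866 without ΔnsiR4 replicate 1), sll0793 (up to 0.0866 without the same array) and slr1260 (up to 0.0916 without WT replicate 1). In limma the deposited values ended the calls of sll0793 (0.103) and slr1260 (0.288), and so did the absence of a filter on dim probes for sll0793 (0.670), slr1260 (0.519) and slr1250 (0.054), normexp correction for slr1260 (0.141) and the fit of only these 4 arrays for slr1260 (0.0714).

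gifA had a level of 5.97 ± 0.56 in ΔnsiR4 against 4.95 ± 1.03 in WT (SD, n = 2 each), a log2 fold change of 1.02 (SE 0.52) that did not pass (limma, adjusted p = 0.399) and ranged from 0.29 without WT replicate 1 to 1.75 without WT replicate 2. gifB had -0.05 (adjusted p = 0.973), glnA -0.72 (0.652), glnN -0.13 (0.919), ntcA 0.23 (0.581), glnB 0.11 (0.818), petE -0.33 (0.424) and petJ 0.05 (0.917). ssr1528 rose by 1.11 (SE 0.19, limma adjusted p = 0.0456). This call was lost without any single array, with adjusted p values from 0.0698 without ΔnsiR4::oex replicate 1 or 2 to 0.259 without ΔnsiR4 replicate 1, and under 7 other settings, with up to 0.115 when only the 4 arrays compared were fitted.

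Besides iron, camera called 6 lists in ΔnsiR4, each lower than WT. Inorganic carbon uptake had a median of -0.35 (adjusted p = 0.000486, and adjusted p = 0.595 with an estimated correlation), with ndhR (sll1594) at -0.66. Cytochrome b6f and mobile carriers had -0.33 (adjusted p = 0.00301, and adjusted p = 0.568 with an estimated correlation), with ferredoxin petF (ssl0020) at -1.45 and petA (sll1317) at -0.71, petF being the 1 member of 10 that passed adjusted over the list alone. Phycobilisome genes had a median of -0.15 (adjusted p = 0.0208, and adjusted p = 0.675 with an estimated correlation), with cpcD (ssl3093) at -0.64. Chaperones and general stress had -0.25 (adjusted p = 0.0208, and adjusted p = 0.675 with an estimated correlation), with superoxide dismutase sodB (slr1516) at -0.82. Glycogen and sugar catabolism had -0.12 (adjusted p = 0.0324, and adjusted p = 0.400 with an estimated correlation), with gnd (sll0329) at -0.64. The 10 measured phosphate response genes had -0.12 (adjusted p = 0.0494, and adjusted p = 0.595 with an estimated correlation), 1 of which, slr1250, was called, and the shift was lost with the deposited values (0.110) and the replicate block (0.0608). Of the 84 measured plasmid genes, ssl7051 rose by 0.90 and sll7002, dim in ΔnsiR4 and without a usable bound, was called lower, calls that leaving out single arrays ended (adjusted p up to 0.223 without ΔnsiR4 replicate 2 and 0.285 without WT replicate 2), as did the deposited values (0.216 for each), and adjusted over the list alone 2 rose and 1 fell. The list itself did not pass (camera, adjusted p = 0.219), nor did nitrogen assimilation (0.0969), ATP synthase (0.0868), photosystem II (0.133), copper response (0.241), arginine and cyanophycin (0.439) or photosystem I (0.843).

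In total 108 of 7714 features were called by limma in ΔnsiR4, 73 higher and 35 lower, or 102 with identical probes counted once, and 93 of the 108 changed by at least 1 on the log2 scale. The count was 42 without ΔnsiR4 replicate 1, 51 without ΔnsiR4 replicate 2, 56 without WT replicate 2 and 56 with the deposited values, and slide and strain cannot be told apart in this comparison.

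**Figure D2:**
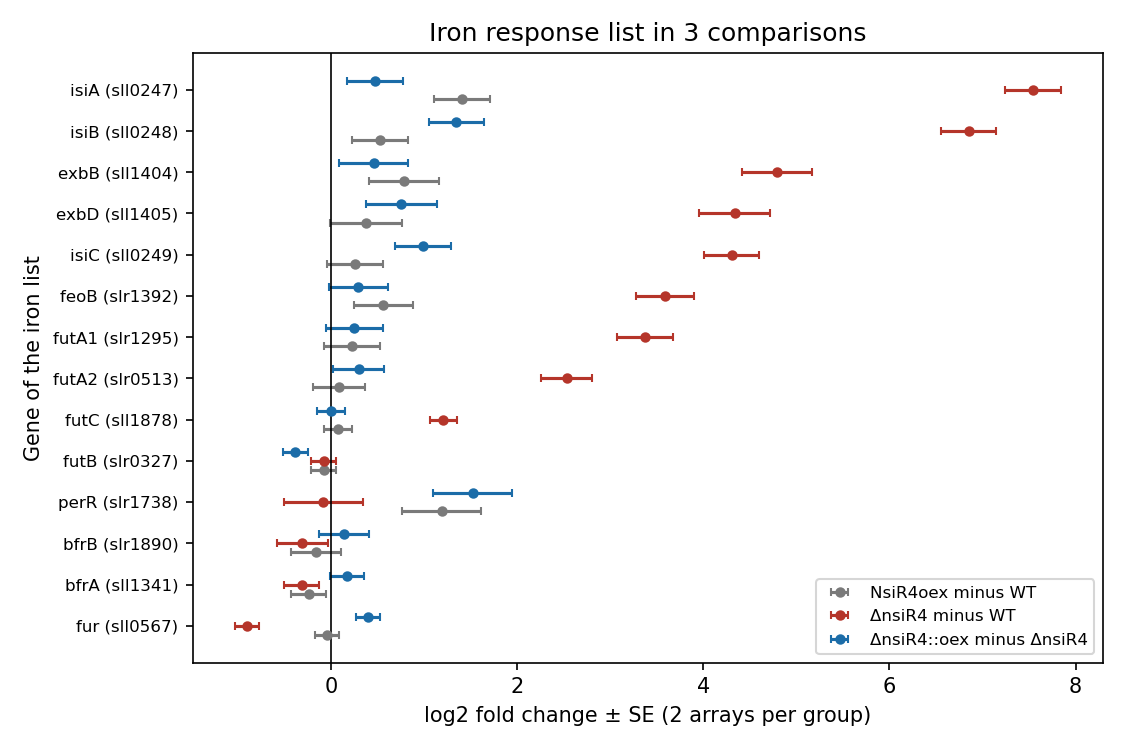
Log2 fold change of the 14 iron list genes (horizontal axis, points with SE, 2 arrays per group) in 3 comparisons, with genes on the vertical axis ordered by ΔnsiR4 minus WT. isiB and exbD, dim in WT, are drawn at their fitted values. isiA stood at 7.54 in ΔnsiR4 minus WT and at 0.47 in ΔnsiR4::oex minus ΔnsiR4.

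Re-expression of NsiR4 from the construct in the deletion background was compared with ΔnsiR4 on the same slide, to ask which changes follow its return. The 4 overlapping features rose most, NC-174 by 8.78 (SE 0.46) and NC-225 by 7.98 (SE 0.47), while NC-171 was at least 344-fold and NC-230 at least 340-fold higher (limma, adjusted p between 0.000833 and 0.000897). NC-578 rose at least 2.28-fold (adjusted p = 0.000897), so that it was called in the same direction in both construct comparisons. Independent lists would share 0.000648 features, but both comparisons use the same estimate of the spread, so these lists are not independent. ssr1528 fell from 3.31 ± 0.24 to 1.44 ± 0.24 (SD, n = 2 each), a log2 fold change of -1.88 (SE 0.19, adjusted p = 0.0233). This fall and its rise in ΔnsiR4 share the ΔnsiR4 arrays, so opposite signs can arise from those arrays alone. sll1358-5'UTR, the leader of a gene that had -1.80 itself, was at least 4.92-fold lower (adjusted p = 0.0185), with 0.129 under normexp correction and 0.386 with the deposited values. The calls of ssr1528 and sll1358-5'UTR ended without any single array of these 2 strains, with adjusted p values up to 0.234 without ΔnsiR4::oex replicate 1 for the former and without ΔnsiR4 replicate 2 for the latter. In limma the call of ssr1528 also ended with the deposited values (0.0708) and the replicate block (0.0516), and that of NC-578 without a filter on dim probes (0.108).

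gifA had a level of 3.84 ± 0.18 in ΔnsiR4::oex against 5.97 ± 0.56 in ΔnsiR4 (SD, n = 2 each), the log2 fold change being -2.13 (SE 0.52). It did not pass when all 8 arrays shared an estimate of the spread (limma, adjusted p = 0.239) and passed when these 4 arrays alone were fitted (adjusted p = 0.0222), the only one of its alternatives in this comparison to do so. gifB had 1.04 (adjusted p = 0.478), and 0.0298 in the fit of the 4 arrays. The remaining genes of the fixed set had adjusted p values of 0.668 for glnN (-0.52), 0.576 for glnB (-0.27), 0.913 for glnA (-0.23), 0.631 for ntcA (-0.21), 0.888 for petJ (-0.07) and 0.665 for petE (0.19).

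Chaperone and general stress genes shifted upward in ΔnsiR4::oex relative to ΔnsiR4. The median log2 fold change of its 20 genes was 0.90 (camera, adjusted p = 8.69e-13, and adjusted p = 0.301 with an estimated correlation). Over all features 0 of them were called by limma, and 13 passed adjusted over the list alone, while 8 were called in the fit of the 4 arrays of this slide. The protease gene htrA (slr1204) had 3.09 (SE 0.55, adjusted p = 0.207, and 0.00403 in the fit of the 4 arrays) and the small heat-shock gene hspA (sll1514) had 2.97 (SE 0.50, adjusted p = 0.187, and 0.0029 in that fit), and both also passed without either NsiR4oex array (adjusted p = 0.0022 and 0.00298). The stress list also differed between the replicates of slide 1, where replicate 2 was higher by a median of 0.43 in WT (19 of 20 genes) and 0.40 in NsiR4oex (16 of 20), against 0.06 in ΔnsiR4 and -0.11 in ΔnsiR4::oex. hspA had -0.13 and 0.39 on the WT arrays and 0.95 and 2.66 on those of NsiR4oex, replicate 1 first. Iron genes shifted upward (median 0.35, adjusted p = 6.35e-05, and adjusted p = 0.301 with an estimated correlation), with perR at 1.52 and isiB at 1.35, and 1 of 14 passed adjusted over the list alone. ATP synthase genes shifted upward (median 0.39, all 9 positive, adjusted p = 0.000196, and adjusted p = 0.755 with an estimated correlation), with atpC (sll1327) at 0.44. Inorganic carbon genes shifted upward (median 0.15, adjusted p = 0.00356, and adjusted p = 0.755 with an estimated correlation), with cmpA (slr0040) at 0.60. Photosystem I genes shifted downward (median -0.34, all 12 negative, adjusted p = 0.0217, and adjusted p = 0.755 with an estimated correlation), with psaE (ssr2831) at -0.74, a shift that missed the threshold with quantile normalization (0.148) and the deposited values (0.0771). No member of these 4 lists was called over all features. Between the WT replicates, replicate 2 minus replicate 1 had a median of -0.59 for photosystem I (2 of 12 higher). It was 0.72 for ATP synthase and 0.38 for inorganic carbon, each with the sign of its shift here, and -0.013 for iron. In ΔnsiR4 and ΔnsiR4::oex this difference was 0.06 and -0.07 for photosystem I and -0.09 and -0.16 for ATP synthase. It was 0.05 and -0.03 for inorganic carbon, and -0.07 and 0.35 for iron. The other 9 lists did not pass, with an adjusted p of 0.933 for nitrogen assimilation, in which adjusted over the list alone nblA1 (ssl0452, 1.52) and nblA2 (ssl0453, 1.08), genes for phycobilisome degradation, rose and gifA fell. Adjusted over the list alone 1 plasmid gene and 1 phosphate gene rose, where the list had an adjusted p of 0.0727 and 0.0734. The adjusted p was 0.147 for cytochrome b6f, 0.543 for copper response, 0.727 for both glycogen and photosystem II, and 0.933 for both phycobilisome and arginine and cyanophycin. In the glycogen list, pfkA1 (sll1196) had -1.70 and glgP1 (sll1356) had -1.48, and both passed in the fit of the 4 arrays (adjusted p = 0.00662 and 0.0403).

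In total 7 features were called by limma in ΔnsiR4::oex against ΔnsiR4, 5 higher and 2 lower, or 6 with identical probes counted once. The 4 overlapping features among them are not separate measurements. Of all features, 256 were called when these 4 arrays alone were fitted, 121 higher and 135 lower, all 7 among them. When WT and NsiR4oex replicate 1 were set with ΔnsiR4 against all other arrays, with slide as a block, 524 features were called, against 2 for the split by construct, so a difference between the replicates of slide 1 ran alongside this comparison. The count was 16 without either WT array, 54 without either NsiR4oex array and 2 when only probes well above background on all 8 arrays were tested, 2 of the 7 being testable there.

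**Figure D3:**
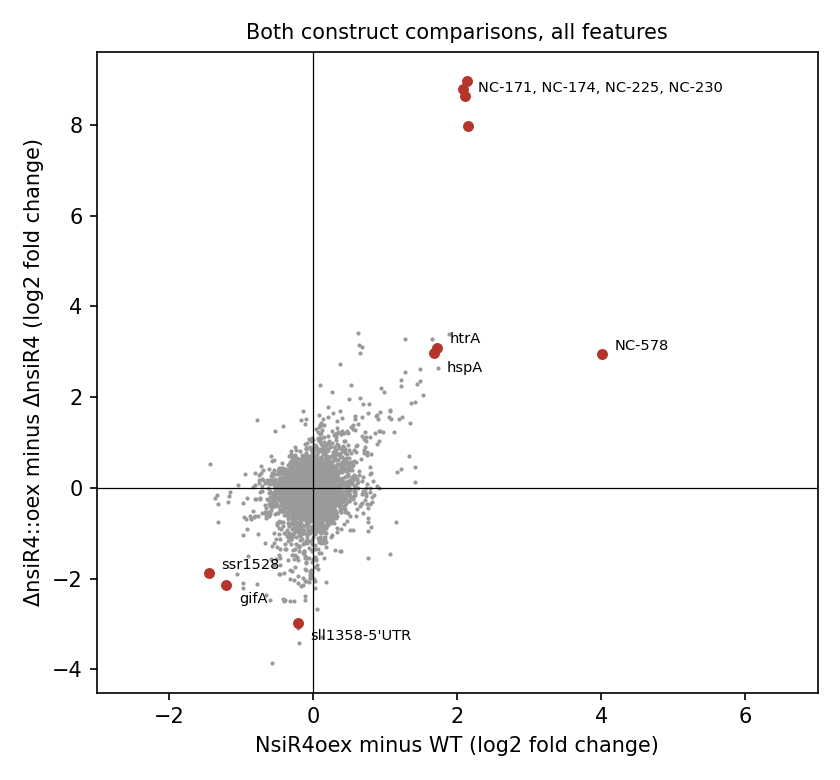
Log2 fold change of 7714 features in NsiR4oex minus WT (horizontal axis) and in ΔnsiR4::oex minus ΔnsiR4 (vertical axis), with named features in red. NC-174 lay at 2.08 and 8.78, ssr1528 at -1.45 and -1.88, and gifA at -1.21 and -2.13.

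ΔnsiR4::oex was also compared with WT, to show how far re-expression returned the strain to the wild-type profile. Iron genes remained far above WT, isiA by 8.01 (SE 0.30, limma adjusted p = 7.95e-05), isiB at least 68.5-fold, isiC by 5.29, exbB by 5.25 and exbD at least 9.69-fold. With the deposited values, exbB had an adjusted p of 0.0706. Of the 14 iron genes 9 rose, and adjusted over the list alone 10 rose and 2 fell, with a median of 3.23 (camera, adjusted p = 4.83e-12, and adjusted p = 0.0621 with an estimated correlation; fry, 0.000283). IsrR-0-x, an antisense RNA to isiA, fell by 5.03 (SE 0.54, adjusted p = 0.0048, and 0.0513 without WT replicate 1) and sll0247-as2, whose probes it shares, fell by 4.77. In ΔnsiR4 against WT, IsrR-0-x had -2.82 (adjusted p = 0.0688). slr1851-5'UTR was at least 3.36-fold, sll1358-5'UTR at least 7.14-fold, NC-262 at least 7.85-fold, sll1831-5'UTR at least 3.11-fold and sll1867-as1 at least 4.26-fold lower, and slr0407-int3 (-2.72), sll1830 (-2.71) and slr1250 (-2.59, probes at -5.59 and 0.41) completed the 10 lowest. The calls of slr1851-5'UTR, sll1831-5'UTR, sll1867-as1 and sll1830 ended without single arrays, with adjusted p values up to 0.250 and 0.259 for slr1851-5'UTR and sll1867-as1 without ΔnsiR4::oex replicate 2, 0.164 for sll1831-5'UTR without WT replicate 1 and 0.0813 for sll1830 without ΔnsiR4::oex replicate 2. With the deposited values, limma gave 0.133 for slr1851-5'UTR, 0.068 for sll1358-5'UTR, 0.134 for sll1831-5'UTR, 0.184 for sll1867-as1 and 0.131 for sll1830, so none of these calls held. Normexp correction (0.0953 and 0.0657) and quantile normalization (0.0529 and 0.0623) also ended those of slr1851-5'UTR and sll1867-as1, and so did the absence of a filter (0.0652 for each).

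Chaperones and general stress lay higher in ΔnsiR4::oex than in WT (median 0.53, camera adjusted p = 0.000282, and adjusted p = 0.864 with an estimated correlation). limma called 0 of 20 over all features, and 9 rose and 1 fell adjusted over the list alone, htrA having 2.42 and hliD (ssr1789) 1.12. Glycogen and sugar catabolism lay lower (median -0.24, adjusted p = 0.0338, and adjusted p = 0.312 with an estimated correlation), with pfkA1 at -1.76 and glgP1 at -1.72, and 1 of 17 fell adjusted over the list alone. Phycobilisome genes lay lower (median -0.27, adjusted p = 0.0374, and adjusted p = 0.894 with an estimated correlation), with cpcG2 (sll1471) at -1.53, a shift missed with quantile normalization (0.409) and the deposited values (0.300). petF fell by 1.46 (adjusted p = 0.0496), a call lost without single arrays, with up to 0.268 without ΔnsiR4::oex replicate 2, with the deposited values (0.109) and with quantile normalization (0.0697), and its list did not pass (0.146). The remaining lists had adjusted p values of 0.0668 for photosystem I, 0.176 for ATP synthase, 0.311 for nitrogen assimilation, 0.383 each for photosystem II and inorganic carbon uptake, 0.647 for arginine and cyanophycin and 0.728 each for copper response, phosphate response and plasmid genes. Adjusted over the list alone, 1 nitrogen gene rose and 1 fell, and 1 phosphate gene rose and 1, slr1250, fell. gifA had -1.11 (adjusted p = 0.304, and -1.84 to -0.38 without single arrays), gifB 1.00 (0.426), glnA -0.94 (0.517), glnN -0.65 (0.538), glnB -0.16 (0.721), petE -0.14 (0.720), petJ -0.03 (0.961) and ntcA 0.02 (0.975).

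In total 132 features were called by limma, 67 higher and 65 lower, or 127 with identical probes counted once, and 82 of the 132 had been called in the same direction in ΔnsiR4, 56 higher and 26 lower. Both comparisons share the WT arrays and the difference between slides, and the overlap that these alone would give was not computed. The fold changes of both comparisons correlated across features at 0.604, and unchanged groups against the same WT arrays gave 0.496 in simulation. The count was 77 without WT replicate 1, 281 without WT replicate 2, 226 without either NsiR4oex array, 80 without ΔnsiR4::oex replicate 1, 66 without replicate 2 and 63 with the deposited values, and slide and strain cannot be told apart.

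Averaged over both backgrounds, the presence of the construct changed 6 features, 5 higher and 1 lower, or 5 when features with an identical probe were counted once. Among them, NC-171, NC-174, NC-225 and NC-230 have overlapping probes and are not separate measurements. NC-174 rose by 5.43 and NC-225 by 5.07, while NC-171 rose at least 38.9-fold and NC-230 at least 38.3-fold (limma, adjusted p = 0.00154 each). NC-578 rose at least 3.33-fold (adjusted p = 0.000124), and ssr1528 fell by 1.66 (SE 0.13, adjusted p = 0.00586). gifA had -1.67 (SE 0.36, adjusted p = 0.321), glnA -0.57 (0.818), glnN -0.40 (0.824), glnB -0.23 (0.744), petJ -0.07 (0.926), ntcA -0.03 (0.967), petE 0.03 (0.972) and gifB 0.74 (0.736). Without NsiR4oex replicate 1, 85 features were called higher and 22 lower, and the count was 26 without NsiR4oex replicate 2 and 2 when only probes well above background on all 8 arrays were tested, which left 2 of the 6 testable. The effect of the construct differed between backgrounds for 0 features in limma, with 469 (6.08%) at an unadjusted p under 0.05. NC-174 was thus not called, although it rose by 2.08 in NsiR4oex and by 8.78 in ΔnsiR4::oex. A count of 0 therefore does not show that the effects were alike. That count was 4 with quantile normalization, 5 without WT replicate 1 and 4 without WT replicate 2.

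Both construct effects share no array, and their log2 fold changes correlated across 7714 features at a Pearson r of 0.324 and a Spearman rho of -0.0055, with 47.8% of features having the same sign. Without NC-171, NC-174, NC-225, NC-230 and NC-578 the Pearson r was 0.259. It was -0.145 without WT replicate 1, -0.0028 without NsiR4oex replicate 2 and 0.638 at its highest, without WT replicate 2. The effects of deletion and overexpression, which share the WT arrays, correlated at a Pearson r of 0.199 (0.513 without WT replicate 1), and 0.497 was obtained in simulation without any effect. Their covariance was 0.0223 against a simulated 0.0270, a difference of -0.0048. With 1 WT array for each comparison, r was -0.261 and -0.051. Features are not independent replicates, so these correlations have no p-value.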

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

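The crossed pairing, the replicate block in the fit of 4 arrays and the count by probe sequence were chosen only after the results were seen. Counts stayed within 1.5 times the reported value except as follows. With only probes well above background on all 8 arrays, 0 features were called in NsiR4oex against WT, 2 in ΔnsiR4::oex against ΔnsiR4 and 2 for the mean construct effect, because the dim called features were then not tested. With the deposited table, 56 were called in ΔnsiR4 and 63 in ΔnsiR4::oex against WT. Quantile normalization gave 4 features for the difference between the construct effects. With only the 4 arrays compared, 256 were called in ΔnsiR4::oex against ΔnsiR4. The cause was not tested for the deposited table, quantile normalization or the fit of 4 arrays. Leaving out single arrays gave 1 to 60 for NsiR4oex, 42 to 97 for ΔnsiR4, 5 to 54 for ΔnsiR4::oex against ΔnsiR4, 66 to 281 for ΔnsiR4::oex against WT, 6 to 1.1e+02 (85 higher and 22 lower) for the mean construct effect and 0 to 5 for the difference, and each such fit assumes that the lone array varies like the other groups. The correlation of both construct effects then ranged from -0.145 to 0.638 and was -0.0028 without NsiR4oex replicate 2, and that of deletion and overexpression ranged from 0.128 to 0.513.

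A replicate block gave 1, 81, 9, 163, 7 and 0 features in the order of the comparisons. With only the 4 arrays compared, it gave 1 in NsiR4oex against WT and 118 in ΔnsiR4::oex against ΔnsiR4. A crossed pairing gave 485 in ΔnsiR4::oex against ΔnsiR4 and 181 against WT (counts of calls only). The differences between replicates correlated at 0.332 between WT and NsiR4oex and at 0.198 between NsiR4oex and ΔnsiR4::oex, and between -0.276 and 0.059 for the other 4 combinations. With 2 replicates the numbers were not taken as pairs, and a pairing of WT with NsiR4oex stays open. The slide block could not change the counts, since each group lay on 1 slide, and could not be fitted for ΔnsiR4 or ΔnsiR4::oex against WT, where slide and strain coincide. For the mean construct effect and the difference, only the arrays compared are all arrays, so that setting was not run. The correlations across features were not run with a replicate block or a trend.

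Of the gene lists, camera called 5, 7, 5 and 4 in the order of the comparisons, 0 in each with an estimated correlation, and fry called 0, 1, 0 and 2. No called list changed direction.

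Among 58 called results of named features, 1007 alternatives gave 106 that were weaker and 2 that reversed. Among 147 that were not called, 2620 alternatives gave 54 that passed and 51 that reversed. Reversals of called values were both in slr1250, whose dim probe was removed by the filter on all 8 arrays, at 0.11 in ΔnsiR4 and 0.41 in ΔnsiR4::oex against WT. All others were in values that had not been called, and the cause was not tested. In ΔnsiR4, slr1898 had 0.051 with the median over probes. In ΔnsiR4::oex against WT, quantile normalization gave sll0199 0.097, sll1796 0.0026 and ssl0707 0.030, the deposited table gave sll0199 0.17 and sll1423 -0.055, normexp gave sll1423 -0.074, the median over probes gave sll1423 -0.035 and sll1796 0.0088, median scaling gave sll1796 0.0064, and no filter gave ssl7021 0.15. Median scaling gave sll1423 0.0069 in the mean construct effect.

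Leaving out single arrays turned these signs, given as lowest to highest. In NsiR4oex the ranges were sll0199 -0.32 to 0.065, sll1515 -0.53 to 1.41, sll1796 -0.25 to 0.12, slr0288 -1.08 to 0.52, slr1756 -2.08 to 0.23, sml0008 -0.66 to 0.063 and ssl0707 -0.46 to 0.054. In ΔnsiR4 they were sll1326 -0.73 to 0.10, sll1515 -1.02 to 0.92, sll1796 -0.14 to 0.23, slr0288 -0.92 to 0.67, smr0005 -0.13 to 1.12 and ssl0707 -0.15 to 0.36. In ΔnsiR4::oex against ΔnsiR4, slr1756 ranged from -0.59 to 0.14. In ΔnsiR4::oex against WT they were sll1325 -0.16 to 0.68, sll1423 -0.11 to 0.14, sll1796 -0.21 to 0.16, slr0288 -1.44 to 0.15 and ssl0707 -0.42 to 0.099. In the mean construct effect they were sll0199 -0.067 to 0.13, sll1423 -0.13 to 0.059, sll1796 -0.16 to 0.025 and slr1756 -1.15 to 0.0021. Signal over background limits the dim features, whose fold changes shrank with normexp and with the deposited table, such as sll1358-5'UTR at -1.63 and -0.75 in ΔnsiR4::oex against ΔnsiR4.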

Other observations

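The tests of the iron genes, of the dependence of the spacers on signal level and of the pairing with the gifA leader, and the splits with slide as a block, were chosen only after the results were seen. Spacer features, the small RNAs of the repeat arrays, varied between replicates and strains. The 14 features of suffix 2 were higher in WT replicate 1 than in WT replicate 2 by a median of 3.60 on the log2 scale (0.71 to 6.38), and by 2.42 in NsiR4oex replicate 1 against replicate 2. The corresponding medians in WT were 0.88 for the 42 features of suffix 0 and 1.71 for the 20 of suffix 1. In ΔnsiR4::oex against ΔnsiR4 the medians were -0.80, -1.36 and -1.67 for suffix 0, 1 and 2, with 0 features called by limma, and 42 of 42, 17 of 20 and 14 of 14 lay lower. So did 40 of 40 tRNA features (median -0.19) and 4965 of all 7714 features.

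NC-186 lies on the opposite strand to NC-578, with matches of 52 and 60 bases between their probes. NC-186 had levels of -2.19 ± 0.17 in WT, -1.60 ± 0.24 in NsiR4oex, -2.49 ± 0.01 in ΔnsiR4 and -1.70 ± 0.21 in ΔnsiR4::oex (SD, n = 2 each).

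The rise of iron genes in both deletion-background strains was weighed against 3 explanations. An array-wide shift between the slides was ruled out, since the list median of 2.95 lay at percentile 100 of 10000 random lists of like level, the highest of which had 0.327. Loss of the small RNA alone, if reversible within 12 h of induction, predicted that the 9 called genes would fall on re-expression. As a set they did not, with a median change of 0.46 (SE 0.14 over genes, which are not replicates) after a rise of 4.30. Of these genes, 8 of 9 lay higher. An effect of the loss that 12 h of re-expression does not undo could not be excluded. Another difference between the 2 pairs of cultures could not be tested, because 0 groups had arrays on both slides.

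The drop of suffix 2 spacers in WT replicate 2 was weighed against 2 technical explanations. A loss of short RNA that took tRNA to a like extent was ruled out, since tRNA features differed by a median of 0.18, a prediction written beforehand. However, 40 of 40 tRNA features, 42 of 42 spacers of suffix 0 and 19 of 20 of suffix 1 also lay higher in WT replicate 1. So did 4652 of all 7714 features. The tRNA features were also far brighter (median 7.83 in WT replicate 1, against 1.97 for suffix 2), so a loss that spared tRNA could not be excluded. A dependence on signal level was ruled out, as the spacer median lay at percentile 100 of 10000 random lists of like level, whose highest was 0.544. No biological explanation was tested.

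As a hypothesis, the 4 overlapping features might be the deleted RNA and pair with the gifA leader. Only the stretches covered by array probes could be paired, 1 probe for the gifA leader, so a pairing site outside them would be missed. The predicted duplex of the 4 features with that probe had -22.1 kcal/mol, and 4.33% of 600 NC features reached that value or lower. Among the probes of 673 leaders, that of gifA ranked 312 for pairing with 63 bases merged from the probes of NC-171 and NC-174. The gifA leader had -22.5 kcal/mol, a value that 47.8% of leaders reached or went below, with a median of -22.1. Among the strongest pairings were thus the 4 features but not the gifA leader. The prediction was met in 1 direction only, and its second criterion was added after the first was seen, so the test decided nothing. A second hypothesis, that leaders with stronger predicted pairing fall more with the construct, was not borne out for these stretches (Spearman rho 0.056, permutation p = 0.153).

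Of the 35 splits of the 8 arrays into 4 and 4, 3 gave as many features as the split by construct, itself included, which gave 1 in a fit of 2 groups. The split by slide gave 333 and the next 121, which points to a structure of the samples. This fit ignores slide and could not exclude chance for its own count of 1. The reported fit of 4 group means called 6 features for the mean construct effect, a count that these splits did not test.

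The splits that take 2 arrays of each slide number 18, too few for a share under 0.05. With slide as a block, the split by construct called 2 features, 2 splits gave as many, itself included, and the highest other gave 524. That split set WT and NsiR4oex replicate 1 with ΔnsiR4, and their replicate 2 with ΔnsiR4::oex. It points to a structure of the samples, in which features that differed between ΔnsiR4 and ΔnsiR4::oex also differed between the replicates of slide 1. The cause was not tested.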
